A study of Mus musculus with 32 samples.

How the data were processed

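The study sequenced RNA of E0771 mouse mammary tumour cells, wild-type or Ddr1 knockout, in culture and as tumours in Rag1-/- and C57BL/6 mice, with 32 libraries in 8 groups. Per the labels' protocols, RNA was taken up in Trizol, about 500 ng entered each library, and libraries followed the Illumina TruSeq stranded mRNA guide. The submitters' processing notes list CASAVA, TopHat, DESeq2 and the mouse build mm10, with no version, role or order. The counting tool, the annotation and whether strand was used in counting are not given in the sources used here. Samples were put in groups by their titles and characteristics, which name the host strain and the treatment and, except at day 6, the cell genotype. The day 6 labels give no Ddr1 genotype.

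The authors deposited 4 tables, one per comparison, whose values per gene and library are of the signal kind, normalized read counts rather than whole counts. In each library these deposited values were whole multiples of 1 step near 1, as gene counts divided by a size factor per library are. Dividing by the step gave whole reads within a tolerance of 0.01 for 100% of values in all 32 libraries, and these recovered reads gave the depth of each library and the RPM. The tables had been normalized separately, so tests were made within a table, and levels set across tables are from separately normalized tables. The design fixed beforehand had allowed for normalized values, and the test it named for them was used. The authors' p-values and adjusted p-values are also in the deposited tables, made before deposit with DESeq2 among the tools in the submitters' processing notes, with the adjustment method not given in the sources used here. At an adjusted p under 0.05 the authors' deposited table counted 276 genes higher and 337 lower in culture, 1019 and 966 in Rag1-/- hosts, 383 and 341 at day 4, and 79 and 76 at day 6. A further 18 columns of group means and fold changes were not used.

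The tables held 22609 genes each in culture and Rag1-/- hosts and 25277 each at day 4 and day 6. In the first pair, 25 symbols had been turned into dates and were left as they stood. Between the table pairs 20109 symbols were shared and 2191 more were paired by RefSeq synonyms. Gene positions, on GRCm38 (the same build as mm10), were taken from the GENCODE annotation by symbol. Of 113 named genes with a position, 24 overlap another protein-coding gene, and 4 overlap one on the same strand (Fgfr2, Gbp4, Gbp6 and Irf9). Their reads are uncertain, as are those of families with close relatives such as the H2, Gbp, Ifit and Oas genes.

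Each comparison was tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(normalized count + 1) over genes with a mean of 10 or more, with the 2 groups of the table alone and no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. A fold change on this scale understates the change of weakly expressed genes. The p-values are two-sided. Gene lists were tested with camera in limma with a preset correlation of 0.01 where at least 5 members were measured, adjusted over the lists of a comparison. The 31 lists, with 460 distinct genes, and the tests, alternatives and naming rule were fixed before the data were examined. No list call held when camera estimated the correlation. A lost call does not by itself show that list members moved together. For hypoxia and glycolysis genes in culture the estimated correlation was 0.00146, below the preset. Even so, their camera p went from 4.91e-05 to 0.0232. Counts of list members were made over all genes and when adjusted over the list alone. The knockout effects in the 2 hosts were compared gene by gene from limma's estimates and standard errors.

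The naming rule took Ddr1 first. It then took up to 8 rises and 8 falls of largest size among called genes with a mean of 50 or more, groups that did not overlap and a symbol that is not a predicted or clone name. For each list past camera it took the 3 members of smallest p, and where fewer than 5 genes passed it took the 5 of smallest p. For the difference between hosts it took the 5 of smallest p in each direction. Of the genes this rule picked, 2 are not reported here, nor included in the check for libraries far from the others. Other genes in the text are said to have been chosen after their values were seen.

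The alternatives were pseudocounts of 0.5 and 5, no filter or a mean of 50, upper-quartile and quantile rescaling, limma without the trend, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, the replicate number as a block, and each library left out in turn. Array weights in limma and fits without the 2 libraries highest in a marker list were added after seeing the data. Those libraries were picked by their own marker levels, so such a fit is no test of these markers. Other tools were Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

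The tests were tried on simulated counts drawn from the real means and library sizes, with 50 genes changed at each fold size. In culture limma recovered 18% of 1.5-fold, 80% of 2-fold, 96% of 4-fold and 98% of 8-fold changes over 11917 genes. In Rag1-/- hosts it recovered 84% of 1.5-fold changes and 100% of the larger ones over 12786 genes. At day 4 it recovered 10%, 48%, 80% and 96% at these sizes over 14051 genes, and at day 6 6%, 26%, 76% and 96% over 14125 genes. Among the unchanged genes it made 16 false calls in culture, 8 in Rag1-/- hosts, 3 at day 4 and 7 at day 6. Camera gave a p under 0.05 for 5, 1, 4 and 1 of 200 unchanged lists in culture, Rag1-/- hosts, day 4 and day 6. The simulated genes were drawn independently, so these rates do not cover lists whose members move together. For real lists the estimated correlation could be high, at 0.946 for adipocyte markers at day 4.

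Depth ran from 18967300 to 39732635 reads per library. The ribosomal RNA gene Rn45s held 4.95% of the reads of day 4 knockout library 3. No pair of libraries within a group was alike within counting noise, with a chi-square per gene of 7.10 or more over 52 pairs. Intervals of read ratios are exact 95% binomial intervals and cover counting error only.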

Results

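RNA from E0771 cells, a mouse mammary carcinoma line of C57BL/6 origin, was sequenced after growth in culture and as tumours in mice. The series' title and design text name the question, which is the role of DDR1 in mammary tumour growth. Ddr1 encodes discoidin domain receptor 1, a receptor tyrosine kinase that binds collagen. In culture, 3 wild-type libraries (parental, empty vector and control cells, named libraries 1, 2 and 3 here) were set against 2 libraries of knockout derivatives (3-6 and 3-7, named libraries 1 and 2). In Rag1-/- hosts, which lack mature T and B cells, 5 wild-type tumours were set against 5 knockout tumours. In C57BL/6 hosts that received tumours grown in Rag1-/- mice, 4 wild-type tumours were set against 5 knockout tumours, titled day 4. A last set of C57BL/6 tumours, titled day 6, held 4 treated with control IgG and 4 treated with an antibody named for the extracellular domain of human DDR1. Depth per library was 29270919 to 37425032 reads in culture, 18967300 to 25516204 in Rag1-/- hosts, 20148955 to 28600639 at day 4 and 20220028 to 39732635 at day 6. Levels are normalized read counts, given as mean ± SD, and fold changes are on the scale of log2(normalized count + 1). Adjusted p-values are from limma with Benjamini-Hochberg adjustment. The labels do not say which libraries came from separate cultures or animals, so p-values measure only the spread between these samples.

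Ddr1 (GRCm38 chromosome 17, 35681567 to 35704621, minus strand), the knockout target, was lower in every knockout library than in every wild-type library of its table. In culture its level was 6387 ± 705 (n = 3) in wild-type and 789.7 ± 177 (n = 2) in knockout cells, and it fell by 3.03 on the log2 scale (SE 0.16, limma adjusted p = 0.00409). It fell by 2.34 in Rag1-/- hosts (SE 0.06, limma adjusted p = 3.88e-11), from 3873 ± 164 to 768 ± 76.6 (n = 5 each). In C57BL/6 hosts at day 4 it fell by 2.23 (SE 0.19, limma adjusted p = 0.00366), from 3563 ± 547 (n = 4) to 774 ± 231 (n = 5). By library, Ddr1 stood in RPM (reads scaled to the library total) at 178, 171 and 213 in wild-type and 26.7 and 19.0 in knockout cells. Tumours in Rag1-/- hosts stood at 187, 189, 175, 179 and 174 when wild-type and at 35.4, 38.0, 33.3, 34.6 and 42.3 when knockout. At day 4 it stood at 132, 175, 159 and 134 in wild-type tumours and at 30.5, 27.9, 31.0, 29.8 and 49.7 in knockout tumours. At day 6 Ddr1 was low with either treatment, at 16.8, 19.5, 22.1 and 15.9 RPM with IgG and 28.5, 18.5, 22.2 and 19.3 with the antibody. The day 6 labels give no Ddr1 genotype for the cells, and levels across tables come from separately normalized tables. The counts are of mouse genes, so they do not show whether human DDR1, for which the antibody is named, was expressed.

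**Figure D1:**
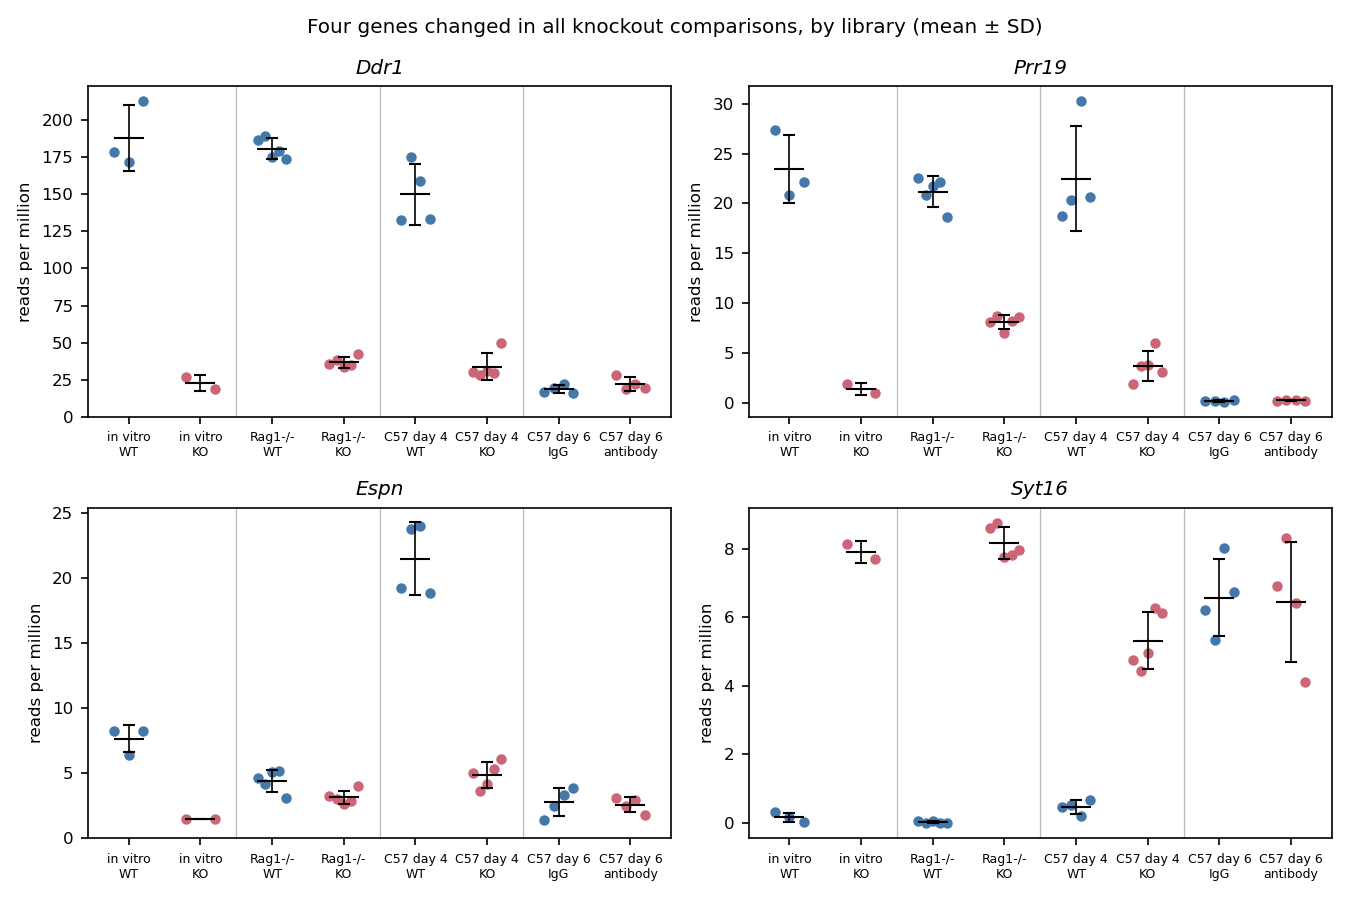
Reads of Ddr1, Prr19, Espn and Syt16 in each library, in RPM, with the mean and SD of each group. Ddr1 averaged 150 RPM in day 4 wild-type tumours, 33.8 in day 4 knockout tumours and 18.6 in day 6 IgG tumours.

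In cultured cells the comparison asked what loss of Ddr1 changed without a host. The knockout cells had lower levels of Tmem176a and Tmem176b, neighbouring genes for membrane proteins, and of Bcam, which encodes a laminin-binding adhesion molecule. They also had lower levels of Lbp, the gene for lipopolysaccharide-binding protein, and of Sod3, the gene for extracellular superoxide dismutase. Of 11911 genes tested, 2 rose and 37 fell, and 33 of the falls exceeded 2-fold. Tmem176a fell by 4.31 (SE 0.35, limma adjusted p = 0.0108), from 2436 ± 569 (n = 3) to 129 ± 69.4 (n = 2). Tmem176b fell by 4.14 (SE 0.33), from 4791 ± 1062.6 to 286 ± 148, also with a limma adjusted p of 0.0108. Their annotated ends overlap on opposite strands, so reads in the overlap are uncertain between them. Prr19 (chromosome 7, 25301411 to 25304132) fell by 4.05 (SE 0.28, limma adjusted p = 0.0108), from 799 ± 122 to 48.8 ± 19.9. Rinl fell from 309 ± 63.0 to 14.4 ± 12.2, with a log2 change of −4.58 ± 0.53 (SE). Cpt1c, a brain-enriched member of the carnitine palmitoyltransferase family, fell from 181 ± 10.96 to 11.8 ± 7.09, a log2 change of −3.95. Lbp fell from 356 ± 149 to 39.9 ± 7.32, Bcam from 449.8 ± 13.0 to 67.8 ± 31.7 and Sod3 from 155 ± 31.2 to 23.3 ± 9.29. Col4a2, a basement membrane collagen and a member of the collagen list, was named after its values were seen and fell by 1.05 on the log2 scale, from 18726 ± 677 to 9048 ± 53.2. The 2 genes that rose were Syt16 (chromosome 12, 73997661 to 74273267), a synaptotagmin family member, and Tmed5, which acts in transport from the endoplasmic reticulum. Syt16 rose from 5.67 ± 4.82 to 274 ± 6.88, a log2 change of 5.71 (SE 0.76, limma adjusted p = 0.0481), and Tmed5 from 2455 ± 83.4 to 4032 ± 327, a log2 change of 0.71 (SE 0.10, limma adjusted p = 0.0499). Groups did not overlap for 4315 genes, 36.2% of those tested, against 20% by chance with 3 and 2 libraries, and 2243 genes had an unadjusted p under 0.05. On recovered reads edgeR called 27 genes (1 higher and 26 lower) and DESeq2 1042 (486 higher and 556 lower). The lean toward falls was weak in DESeq2 and absent in limma without wild-type library 1, with 905 higher and 750 lower. The count moved with single libraries, to 1655 without wild-type library 1, 2 without wild-type library 2, 7 without wild-type library 3, 8 without knockout library 1 and 4 without knockout library 2. Without wild-type library 2, each gene picked by the naming rule except Ddr1 lost its call, at limma adjusted p from 0.0531 for Prr19 to 0.232 for Tmed5. Lost calls had limma adjusted p from 0.0719 (Lbp) to 0.208 (Tmed5) without wild-type library 3, from 0.125 (Lbp) to 0.248 (Syt16) without knockout library 1, and from 0.0866 (Bcam) to 0.223 (Syt16) without knockout library 2. Fitted without the trend, only Ddr1 and Prr19 of the genes named here by the rule kept their calls. The others had limma adjusted p of 0.0650 for Tmem176a, Tmem176b and Cpt1c, 0.0655 for Bcam, 0.0718 for Sod3, 0.0786 for Lbp, 0.0827 for Rinl, 0.0992 for Syt16 and 0.103 for Tmed5. Syt16 was also at 0.0538 with a pseudocount of 0.5, 0.0542 with no filter, 0.0569 with a mean of 50 or more and 0.0513 with upper-quartile rescaling. Tmed5 was at 0.0506 with that pseudocount, 0.0570 with no filter, 0.0531 with a mean of 50 or more and 0.0602 in edgeR. Sod3 was at 0.0592 with no filter, 0.0567 with a mean of 50 or more, 0.0691 after quantile normalization and 0.0651 in edgeR, and Lbp at 0.0572 in edgeR.

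Among 17 gene lists tested in culture, those of hypoxia with glycolysis and of the interferon response were lower in the knockout cells. Of 15 measured hypoxia and glycolysis genes, 2 lay above 0, and the median log2 change was −0.35 (camera adjusted p = 0.000835, and adjusted p = 0.395 with an estimated correlation). No member passed the limma test over all genes, and 9 fell when adjusted over the list alone. Pfkfb3, a regulator of glycolysis, was at −0.54, Adm, the gene for adrenomedullin, at −0.49, and the stress-response gene Ndrg1 at −0.45, each with a limma adjusted p of 0.0686 over all genes. Of 24 interferon response genes, 1 lay above 0 and the median was −0.97 (camera adjusted p = 0.003, and adjusted p = 0.812 with an estimated correlation). None changed over all genes or when adjusted over the list alone. The guanylate-binding protein genes Gbp5 and Gbp6 were at −1.73 and −1.86, with limma adjusted p of 0.131 and 0.134. As a mean log2 level per library, the interferon list stood at 8.48, 6.30 and 6.49 in wild-type and 5.75 and 6.43 in knockout cells. The camera adjusted p of that list was 0.209 without wild-type library 1 and 0.146 without knockout library 1, with medians of −0.16 and −0.55. Its median was −1.55 without wild-type library 2 and −1.54 without knockout library 2. The other 15 lists had camera adjusted p from 0.0791, for MHC class I presentation, to 0.814.

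For tumours in Rag1-/- hosts the comparison asked what the knockout changed in tumours without mature T and B cells. Knockout tumours had lower levels of Dpt, the gene for the matrix protein dermatopontin, of Igfbp5, which encodes a binding protein of insulin-like growth factors, and of Wisp2, a matricellular gene. They had higher levels of Greb1, a gene regulated by oestrogen, of the sodium-hydrogen exchanger gene Slc9a2 and of Map2k6, a kinase that activates p38. Of 12795 genes tested, 1441 rose and 1463 fell, with 130 of the rises and 30 of the falls above 2-fold. Dpt fell by 1.10 on the log2 scale (SE 0.14, limma adjusted p = 0.000128), from 5212 ± 1063.5 to 2403 ± 355 (n = 5 each). Igfbp5 fell by 1.56 (SE 0.20), from 281 ± 70.9 to 95.1 ± 23.6, and Wisp2 by 1.33 (SE 0.17), from 656 ± 138 to 262 ± 68.4. Ly6c1, which encodes a surface antigen of monocytes and endothelial cells, fell by 0.93, from 1384 ± 151 to 724 ± 71.7. Prr19 fell by 1.42 (SE 0.09, limma adjusted p = 9.61e-07), from 454 ± 37.9 to 169.7 ± 14.9, and its neighbour Tmem145 (chromosome 7, 25306106 to 25316195) by 1.49. Cpt1c and Tmem176b fell by 1.13 and 0.95. Syt16 was at 0.445 ± 0.609 in wild-type and 171 ± 10.6 in knockout tumours (limma adjusted p = 4.42e-09). With 2 reads in all wild-type tumours and 869 in all knockout tumours, the Syt16 ratio was 438, with an exact 95% counting interval of 121 to 3619. Tex19.2, a germ-cell gene, rose by 4.01 (SE 0.31), from 19.6 ± 11.2 to 296 ± 49.5. Greb1 rose by 2.85 (SE 0.19), from 40.7 ± 13.4 to 289 ± 34.5, and Slc9a2 by 2.77 (SE 0.19), from 152 ± 53.8 to 1021 ± 199. Acpp, the gene of prostatic acid phosphatase, rose by 2.65, Map2k6 by 2.64, Hectd2 by 2.45 and Chn1, which encodes a regulator of Rac, by 2.36. Groups did not overlap for 1918 genes, 14.99% of those tested, against 0.794% by chance.

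Among 27 lists tested in Rag1-/- hosts, MHC class I presentation, the interferon response and collagens were lower in knockout tumours. Of 14 MHC class I presentation genes, 6 fell over all genes and 6 when adjusted over the list alone, and the median was −0.27 (camera adjusted p = 0.000704, and adjusted p = 0.908 with an estimated correlation). The proteasome subunit gene Psmb9 fell by 0.61, the peptide transporter gene Tap1 by 0.47 and H2-D1 by 0.30, with limma adjusted p of 0.000313, 0.00124 and 0.00125. Psmb9 and Tap1 overlap on opposite strands and H2-D1 has close relatives, so their reads are uncertain. Psmb9, Tap1 and H2-D1 start at 34181987, 34187553 and 35262730 on chromosome 17, near Ddr1 at 35681567. On that chromosome 99 genes fell and 41 rose in Rag1-/- hosts, with a median of −0.06 over 634 genes. Whether position bears on these falls was not tested. Quantile normalization put H2-D1 at −0.11 (limma adjusted p = 0.0515). Of 26 interferon response genes, 6 fell over all genes and 11 when adjusted over the list alone, with a median of −0.29 (camera adjusted p = 0.0178, and adjusted p = 0.908 with an estimated correlation). Irf9, part of the interferon-activated transcription complex, fell by 0.31, and the oligoadenylate synthetase family genes Oas2 and Oasl2 by 0.52 and 0.50. Of 18 collagen genes, 4 fell over all genes and 6 when adjusted over the list alone, with a median of −0.31 (camera adjusted p = 0.0384, and adjusted p = 0.908 with an estimated correlation). Col16a1 fell by 0.35, Col4a2 by 0.36 and Col18a1 by 0.33. The camera adjusted p of the collagens was 0.114 without wild-type library 2, 0.0674 without wild-type library 5, 0.133 without knockout library 1, 0.106 without knockout library 4 and 0.147 after quantile normalization. That of the interferon response was 0.101 without wild-type library 5 and 0.140 without knockout library 1. Col18a1 had a limma adjusted p of 0.0550 without wild-type library 3 and 0.0501 without wild-type library 4. Oasl2 lost its call without wild-type libraries 1, 2, 3 and 5, at 0.0698, 0.0714, 0.0565 and 0.0641, and without knockout libraries 1, 2 and 4, at 0.0695, 0.0595 and 0.0711. Without the trend, Col18a1 was at 0.0541 and Oasl2 at 0.0747.

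The other lists in Rag1-/- hosts did not pass camera, although single members changed by limma. In these lists the genes named next were chosen after their values were seen. Among 22 matrix proteases and inhibitors, 6 rose and 1 fell over all genes (camera adjusted p = 0.176). The collagenase gene Mmp13 rose by 0.91, the plasminogen activator genes Plat and Plau by 1.04 and 0.47, and Adamts12 by 1.13, while Mmp11 fell by 0.45. Of 10 MHC class II presentation genes, 3 fell over all genes and 6 when adjusted over the list alone (median −0.51, camera adjusted p = 0.052), with Cd74 down by 0.69 and H2-Ab1 by 0.65. In edgeR on recovered reads 1 of 9 members tested fell. Among 5 luminal epithelial genes the adhesion gene Epcam rose by 2.15 and the transcription factor gene Elf3 by 0.82 (camera adjusted p = 0.453). Of 20 cell cycle genes 4 fell (camera adjusted p = 0.051), among them Cdc20 by 0.42 and Plk1 by 0.30. Of 12 p53 target genes 4 rose and 3 fell (camera adjusted p = 0.654), with Cdkn1a up by 0.39 and Bax down by 0.39. Of 16 macrophage and monocyte markers 2 rose and 1 fell (camera adjusted p = 0.59), the mannose receptor gene Mrc1 up by 0.64 and Ly6c2 down by 0.65. Of 14 fibroblast markers 13 lay below 0, with a median of −0.29, and 3 fell and 1 rose over all genes (camera adjusted p = 0.168). Of the 2 red blood cell genes measured, too few for camera, 1 rose over all genes, and their mean log2 level was above every wild-type library in 4 of 5 knockout libraries. Camera adjusted p was 0.608 for 14 endothelial markers, 0.121 for 9 adipocyte markers, 0.992 for 5 T cell markers, 0.902 for 8 natural killer cell markers, 0.117 for 12 cytotoxic effector genes, 0.453 for 6 neutrophil markers, 0.168 for 9 dendritic cell markers and 0.621 for 8 regulatory T cell and checkpoint genes. It was 0.363 for collagen processing and cross-linking, 0.363 for matrix glycoproteins and proteoglycans, 0.992 for collagen receptors (median 0.07 with a mean of −0.18, tested lower) and 0.459 for lymphocyte-attracting chemokines. As a mean log2 level per library, adipocyte markers averaged 5.77 ± 1.32 in wild-type and 4.16 ± 2.19 in knockout tumours, with ranges of 3.74 to 7.05 and 2.62 to 7.78.

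In C57BL/6 hosts at day 4 the comparison asked what the knockout changed in tumours moved into mice with an intact immune system. Beside Ddr1, the knockout tumours had lower levels of Espn, which encodes an actin-bundling protein, of Prr19 and of Nptx1, the gene for neuronal pentraxin 1, and a higher level of Syt16. Luminal epithelial, keratinocyte and adipocyte markers were also higher as groups, and hypoxia genes lower, in camera with the preset correlation only (adjusted p = 0.407, 0.472, 0.533 and 0.472 with an estimated one). Of 14105 genes tested, 1 rose and 4 fell in limma, and each change exceeded 2-fold. Espn (chromosome 4, 152120331 to 152152371) fell by 2.21 (SE 0.20, limma adjusted p = 0.00366), from 510.5 ± 75.5 (n = 4) to 110.5 ± 25.1 (n = 5). Prr19 fell by 2.73 (SE 0.32, limma adjusted p = 0.0199), from 535 ± 134 to 84.3 ± 34.9. Nptx1 (chromosome 11, 119538719 to 119547753) fell by 1.44 (SE 0.19, limma adjusted p = 0.0471), from 5253 ± 985 to 1953 ± 426. Syt16 rose by 3.43 (SE 0.34, limma adjusted p = 0.00642), from 10.98 ± 4.65 to 121 ± 22.5. Groups did not overlap for 813 genes, 5.76% of those tested, against 1.59% by chance, and 2116 genes had an unadjusted p under 0.05. On recovered reads edgeR called 4 genes and DESeq2 724. The count was 13 without wild-type library 1, 3 without wild-type library 2, 3 or 4, 11 without knockout library 3 and 50 without knockout library 5. Prr19 had limma adjusted p of 0.120, 0.102, 0.116 and 0.0636 without wild-type libraries 2, 3 and 4 and knockout library 2. Nptx1 had 0.199, 0.107, 0.157 and 0.186 without wild-type libraries 2, 3 and 4 and knockout library 1, 0.0543 in edgeR and 0.0690 without the trend. Without the 2 libraries highest in muscle markers, an exclusion added after seeing the data, Prr19 was at 0.0624 and Nptx1 at 0.0976.

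Among 29 lists tested at day 4, 7 were higher and 4 lower in knockout tumours, with no member past the limma test over all genes in any of the 11. Of 16 luminal epithelial genes 14 lay above 0, with a median log2 change of 3.37 and 12 higher when adjusted over the list alone (camera adjusted p = 5.6e-09, and adjusted p = 0.407 with an estimated correlation). The keratin gene Krt18 was at 16.2 ± 7.93 and 520.1 ± 401 (n = 4 and 5), the tight junction gene Cldn4 at 2.60 ± 3.08 and 161 ± 97.2, and the epithelial splicing regulator gene Esrp2 at 5.22 ± 1.29 and 33.9 ± 16.0. All 11 basal and skin keratinocyte markers lay above 0, with a median of 2.11, and 4 were higher when adjusted over the list alone (camera adjusted p = 5.17e-05, and adjusted p = 0.472 with an estimated correlation). Krt14, Krt5 and Trp63, genes of basal epithelium, were at log2 changes of 5.23, 7.44 and 3.34, and the list median was 1.31 without knockout library 3. Krt14 was far higher in knockout library 3, and Cldn4 far lower in knockout library 5, than in the other knockout libraries. All 11 adipocyte markers lay above 0, with a median of 3.65 and none past the limma test when adjusted over the list alone (camera adjusted p = 4.38e-05, and adjusted p = 0.533 with an estimated correlation). Fabp4, a fatty acid carrier gene, was at 2319 ± 1388 and 18809 ± 19829, and the lipid droplet gene Plin4 and the carbonic anhydrase gene Car3 at log2 changes of 3.65 and 4.15. Mean log2 levels of the luminal list were 3.49, 3.09, 3.63 and 3.68 in wild-type libraries and 7.43, 7.64, 5.48, 7.50 and 4.43 in knockout libraries. For the keratinocyte list they were 3.81, 3.02, 3.98 and 3.70 against 6.31, 5.45, 9.41, 5.58 and 4.56. Adipocyte levels overlapped, at 9.54, 4.04, 6.33 and 5.33 against 9.02, 12.68, 8.58, 12.27 and 6.11. Skeletal muscle markers were at 10.08 in wild-type library 3 and 11.28 in knockout library 5 and between 3.42 and 7.66 in the others (camera adjusted p = 0.887 for 13 markers).

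Endothelial markers at day 4 had 14 of 14 members above 0, a median of 1.27 and 6 higher when adjusted over the list alone (camera adjusted p = 4.69e-07, and adjusted p = 0.472 with an estimated correlation). The vessel genes Ptprb, Plvap and Tie1 were at log2 changes of 1.70, 1.68 and 1.58, and mean list levels were above every wild-type library in 3 of 5 knockout libraries. Of 14 fibroblast markers 13 lay above 0, with a median of 0.78 and 0 past the limma test when adjusted over the list alone (camera adjusted p = 0.0148, and adjusted p = 0.685 with an estimated correlation). Acta2 and Tagln, genes of contractile fibroblasts and smooth muscle, were at 0.82 and 1.09 and the surface antigen gene Thy1 at 0.86. All 26 interferon response genes lay above 0, with a median of 0.50 and none past limma when adjusted over the list alone (camera adjusted p = 1.85e-05, and adjusted p = 0.685 with an estimated correlation). Gbp4, Gbp2 and Gbp3 were at 1.14, 0.87 and 0.92. Of 20 cell cycle genes 18 lay above 0, with a median of 0.30 and none past limma when adjusted over the list alone (camera adjusted p = 0.00125, and adjusted p = 0.685 with an estimated correlation). The DNA synthesis genes Tyms, Mcm6 and Mcm3 were at 0.55, 0.31 and 0.35. These groups moved in the same tumours as the epithelial and adipocyte markers, whose lists had medians of 3.37 and 3.65. The fibroblast list lost its call without wild-type library 3 (camera adjusted p = 0.0628), knockout library 1 (0.0875) and knockout library 4 (0.0859), and the cell cycle list without wild-type library 4 (0.0508) and knockout library 3 (0.0628). Medians moved by over 1.5 times to 0.80 for endothelial markers without wild-type library 1, to 0.33 for interferon response genes without knockout library 2, and to 0.17 and 0.20 for cell cycle genes without wild-type library 4 and knockout library 3. Red blood cell genes, with 3 measured and so too few for camera, had a median of 3.31, and 3 were higher when adjusted over the list alone. Their mean log2 level was 3.23 ± 0.444 in wild-type and 6.05 ± 0.990 in knockout tumours, above every wild-type library in 5 of 5 knockout libraries.

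Of 16 hypoxia and glycolysis genes at day 4 all lay below 0, with a median of −0.59, and all 16 were lower when adjusted over the list alone (camera adjusted p = 3.21e-10, and adjusted p = 0.472 with an estimated correlation). The carbonic anhydrase gene Car9 was at 2342 ± 292 and 1203 ± 350 (n = 4 and 5), and Ndrg1 and the oxygen-sensing enzyme gene Egln3 at −0.79 and −0.73. The mean log2 level of the list was below that of every wild-type library in 5 of 5 knockout libraries. Of 14 immediate early and heat shock genes 3 lay above 0, with a median of −0.25 and 2 lower when adjusted over the list alone (camera adjusted p = 0.00288, and adjusted p = 0.472 with an estimated correlation). Ier3, Dusp1 and Fosb, early response genes, were at −0.65, −0.73 and −0.69. Of 15 TGF-beta and YAP target genes 3 lay above 0, with a median of −0.19 and 3 lower when adjusted over the list alone (camera adjusted p = 0.0199, and adjusted p = 0.472 with an estimated correlation). Tgfbi and Tgfb1 were at −0.70 and −0.35. Of 12 mesenchymal transition genes 2 lay above 0, with a median of −0.28 and 1 lower when adjusted over the list alone (camera adjusted p = 0.0231, and adjusted p = 0.407 with an estimated correlation). The receptor kinase gene Axl, which is on both of these lists, was at −0.56, Snai1 at −0.31 and Prrx1 at −0.46. Axl and Tgfb1 lie in a segment of chromosome 7, described below, whose genes had a median of −0.19 at day 4. The mesenchymal list lost its call after quantile normalization (camera adjusted p = 0.148), without wild-type library 3 (0.0517) and without knockout library 3 (0.0642), and the TGF-beta and YAP list after quantile normalization (0.117) and without knockout library 3 (0.0574). The median of the TGF-beta and YAP list was −0.31 without wild-type library 3, −0.11 without wild-type library 4 and −0.13 without knockout library 2. Luminal and adipocyte markers, with medians of 3.37 and 3.65, were higher in the same tumours. Red blood cell genes, described with the endothelial markers, were higher there too. Among the lists that did not pass, camera adjusted p was 0.23 for 11 T cell markers, 0.847 for 13 cytotoxic effector genes, 0.128 for 5 B cell markers, 0.347 for 17 macrophage and monocyte markers, 0.853 for 15 MHC class I presentation genes and 0.853 for 20 collagens. The lowest camera adjusted p with 1 library left out was 0.0172, 0.171, 0.0357, 0.0172, 0.301 and 0.427 for these lists in turn.

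**Figure D2:**
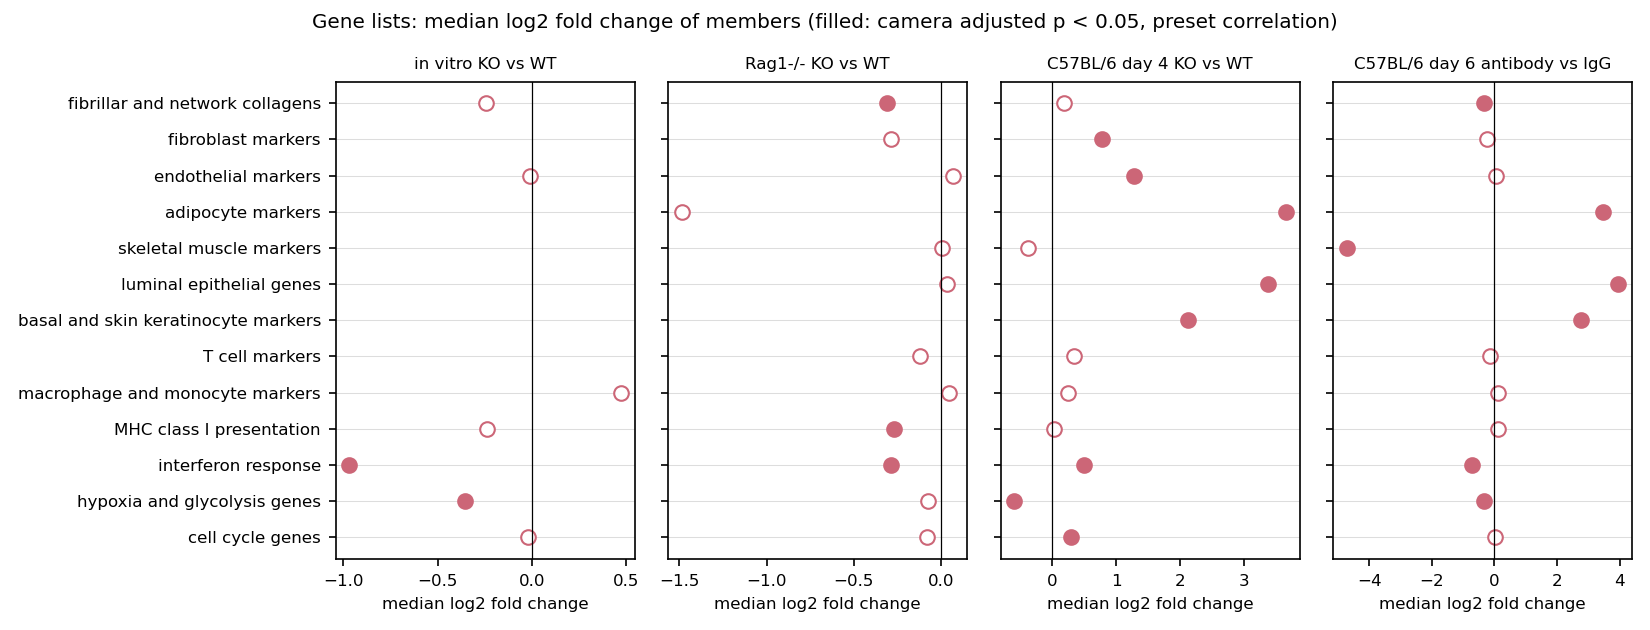
Median log2 fold change of the measured members of each gene list in the 4 comparisons, with filled points where camera's adjusted p was under 0.05. The luminal epithelial list had medians of 3.37 at day 4 and 3.96 at day 6.

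At day 6 the comparison asked what antibody treatment changed in C57BL/6 tumours. Muscle markers were lower and luminal, keratinocyte and adipocyte markers higher as groups in antibody-treated tumours in camera with the preset correlation only (adjusted p = 0.741 for each with an estimated one), while no single gene passed the limma test. Of 14155 genes tested, 0 changed by limma and 0 by edgeR, 155 by DESeq2 (79 higher and 76 lower), and 1218 had an unadjusted limma p under 0.05. Ddr1 was at 554 ± 89.0 with IgG and 657 ± 133 with the antibody (n = 4 each, log2 change 0.24, limma adjusted p = 0.584). The genes of smallest p did not pass, at a limma adjusted p of 0.517. Bmp7, a growth factor of the TGF-beta family, was at 1342 ± 67.2 with IgG and 703 ± 131 with the antibody. Map7 was at 185 ± 28.9 and 67.3 ± 23.3, and Sncg at 99.9 ± 17.7 and 403 ± 221. Clca3a2 was at 1.25 ± 0.947 and 181 ± 131, and Fgfr2, a fibroblast growth factor receptor gene, at 9.38 ± 1.57 and 226 ± 246. Groups did not overlap for 552 genes, 3.90% of those tested, against 2.86% by chance. Without antibody library 1, limma called 5 genes, all higher.

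Among 29 lists tested at day 6, 3 were higher and 4 lower with the antibody, and no member changed over all genes. All 16 luminal epithelial genes lay above 0, with a median log2 change of 3.96, and 13 were higher when adjusted over the list alone (camera adjusted p = 5.29e-12, and adjusted p = 0.741 with an estimated correlation). Cldn3 was at 2.27 ± 2.22 with IgG and 144 ± 156 with the antibody (n = 4 each), and Krt19 at 25.0 ± 23.3 and 1477 ± 1724. All 13 basal and skin keratinocyte markers lay above 0, with a median of 2.76 (2.77 with the members at 0 in a whole group set to a floor of 3 reads over that group), and 1 was higher when adjusted over the list alone (camera adjusted p = 3.63e-06, and adjusted p = 0.741 with an estimated correlation). Krt14, Krt17 and Sbsn were at 4.58, 2.79 and 0.62, and the list median was 1.06 without antibody library 3. Of 11 adipocyte markers 10 lay above 0, with a median of 3.48 and 2 higher when adjusted over the list alone (camera adjusted p = 3.18e-05, and adjusted p = 0.741 with an estimated correlation). Fabp4 and the adipokine gene Retn were at 1.97 and 4.04, and Lep, the gene for leptin, had 3 reads with IgG and 299 with the antibody, a ratio of 82.0 with an exact 95% counting interval of 27.8 to 399.8. All 13 skeletal muscle markers lay below 0, with a median of −4.72, and 13 were lower when adjusted over the list alone (camera adjusted p = 1.02e-10, and adjusted p = 0.741 with an estimated correlation). Myl1, Myh4 and Acta1, genes of muscle fibres, were at −4.72, −5.13 and −4.99. Mean log2 levels of the luminal list were 2.88, 3.53, 2.98 and 3.68 with IgG and 4.19, 7.97, 5.58 and 8.83 with the antibody, and those of the muscle list 11.34, 13.93, 8.48 and 9.85 against 7.31, 3.51, 9.12 and 4.89.

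All 26 interferon response genes at day 6 lay below 0, with a median of −0.72 and none past limma when adjusted over the list alone (camera adjusted p = 1.02e-10, and adjusted p = 0.741 with an estimated correlation). Ifit2 was at 5071 ± 1160.4 with IgG and 2769 ± 922 with the antibody (n = 4 each), and Ifit3 and Stat2 at log2 changes of −0.52 and −0.82. Mean list levels were 11.70, 12.14, 12.25 and 11.85 with IgG and 11.38, 10.80, 11.44 and 11.50 with the antibody. Of 20 collagens 2 lay above 0, with a median of −0.33 and none past limma when adjusted over the list alone (camera adjusted p = 0.0054, and adjusted p = 0.741 with an estimated correlation). Col12a1 and Col8a1 were at −1.13 and −0.96, and the basement membrane gene Col4a5 at 2.37. Of 16 hypoxia and glycolysis genes 2 lay above 0, with a median of −0.34 and none past limma when adjusted over the list alone (camera adjusted p = 0.00412, and adjusted p = 0.822 with an estimated correlation). Adm, the vessel growth factor gene Vegfa and the hexokinase gene Hk2 were at −0.87, −0.53 and −0.33. Luminal and muscle markers, with medians of 3.96 and −4.72, moved in the same tumours. The collagen list had a camera adjusted p of 0.0917 without antibody library 2 and 0.0537 without antibody library 4, where its median was −0.18. Without the 2 libraries highest in luminal genes, an exclusion added after seeing the data, the collagen list turned to higher (camera adjusted p = 0.726). The hypoxia list had 0.265 without IgG library 3, where its median was −0.16, and 0.0537 without antibody library 4. T cell markers were at mean log2 levels of 5.81, 8.91, 8.60 and 8.498 with IgG and 6.12, 7.15, 8.10 and 9.995 with the antibody (camera adjusted p = 0.911 for 16 markers). With 1 library left out, their camera adjusted p ranged from 0.00697 to 0.972 and their median from −0.89 to 0.46. Camera adjusted p was 0.853 for 15 cytotoxic effector genes, 0.853 for 9 natural killer cell markers, 0.853 for 9 B cell markers and 0.198 for 10 MHC class II presentation genes. The lowest camera adjusted p with 1 library left out was 0.00517, 0.0141, 0.359 and 0.00218 for these lists in turn.

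**Figure D3:**
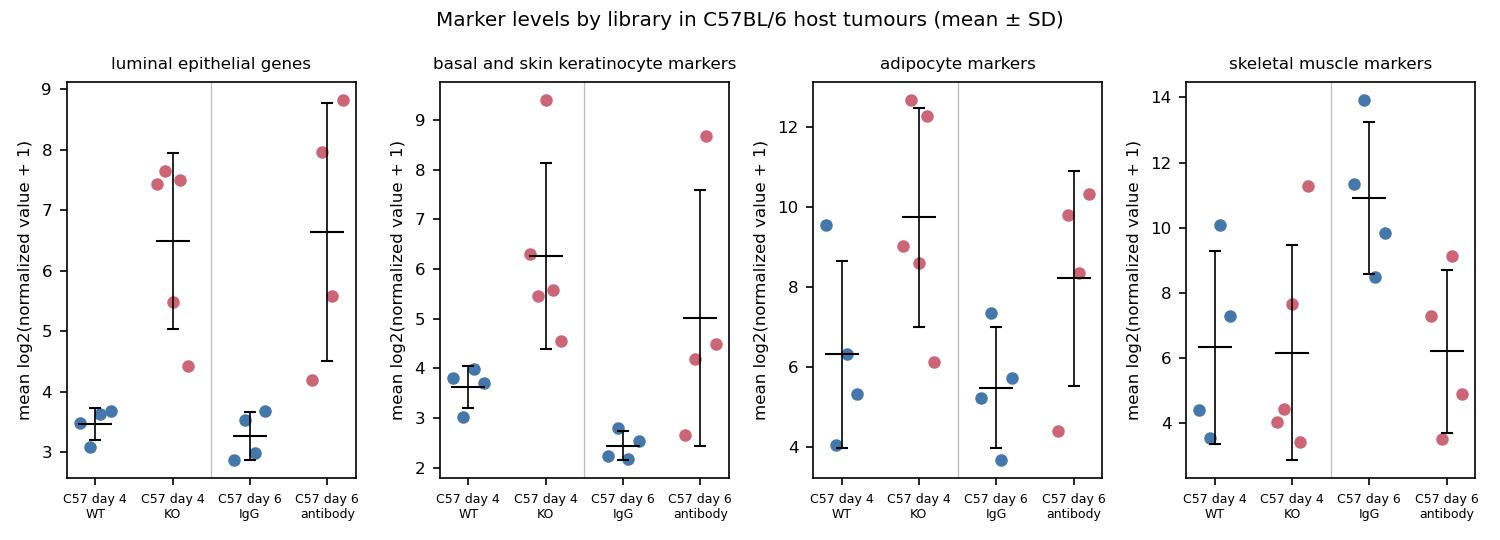
Mean log2(normalized count + 1) of 4 marker lists in each C57BL/6 tumour at day 4 and day 6. Luminal levels ran from 3.09 to 3.68 in day 4 wild-type tumours and from 4.43 to 7.64 in day 4 knockout tumours.

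The knockout effect in C57BL/6 hosts was set against that in Rag1-/- hosts by a test of the difference itself over 12404 genes. The effect differed for 336 genes, higher in C57BL/6 hosts for 37 and lower for 299. The adhesion gene Jup had log2 changes of −0.51 in Rag1-/- and 0.99 in C57BL/6 hosts, a difference of 1.499 (SE 0.24, adjusted p = 0.00125 from limma's standard errors). Acta2 had changes of −0.50 and 0.82, a difference of 1.32, the receptor-like gene Ptk7 −0.61 and 0.34, the desaturase gene Fads1 −0.27 and 0.38, and the calcium channel gene Cacna1a −0.61 and 1.53. Slc9a2 had changes of 2.77 and −0.30, a difference of −3.07 (adjusted p = 1.66e-05 from limma's standard errors). Chn1 had changes of 2.36 and 0.01, Map2k6 2.64 and −0.91, Rnf165 2.35 and −0.26, and Tex19.2 4.01 and 0.89. The host, the transplant history and the table, normalized separately, differed together in this comparison. Day 4 knockout tumours also had higher luminal, keratinocyte and adipocyte lists, with medians of 3.37, 2.11 and 3.65. The test does not separate such differences in marker levels from a knockout effect within the tumour cells.

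Ddr1, Espn and Prr19 fell and Syt16 rose in all 3 knockout comparisons. In culture and Rag1-/- hosts together, 23 genes fell in both and 2 rose in both, against 4.48 and 0.245 for independent lists, while Ngef and Selenop changed in opposite directions. Of 37 genes changed in culture that were also tested in the other tables, 33 had the same sign in Rag1-/- hosts and 23 at day 4. Across 11490 genes, which are not independent replicates, Pearson's r of the log2 changes was 0.455 between culture and Rag1-/- hosts (Spearman 0.418). Between culture and day 4 it was −0.0147 (Spearman 0.0977), and between Rag1-/- hosts and day 4 it was −0.0151 (Spearman 0.0236). Between the day 4 knockout and the day 6 antibody comparisons it was 0.431 (Spearman 0.261), and between Rag1-/- hosts and day 6 it was −0.155 (Spearman −0.204).

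Genes of a segment of chromosome 7 lay below 0 together in culture and in Rag1-/- hosts. Between 20 and 50 Mb of chromosome 7, 93.1% of 288 genes were below 0 in culture, with a median log2 change of −0.41, against 48.3% of the other genes, and 9 of the 37 genes that fell lay there. In Rag1-/- hosts 90.2% of 297 genes were below 0, with a median of −0.29, against 49.9% of the others, and the segment held 153 of the 1463 genes that fell. At day 4 the median was −0.19 over 339 genes, 72.0% of them below 0, and at day 6 it was 0.12 over 334 genes. Prr19, Tmem145, Rinl and Cpt1c lie in this segment, which was singled out after its values were seen. Axl and Tgfb1, at −0.56 and −0.35 at day 4, lie there too. Chromosome 5 had a median of 0.34 over 746 genes in culture and 0.10 in Rag1-/- hosts, where 185 of its genes rose and 27 fell. At day 4 its median was −0.01, with 50.7% of 873 genes below 0.

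**Figure D4:**
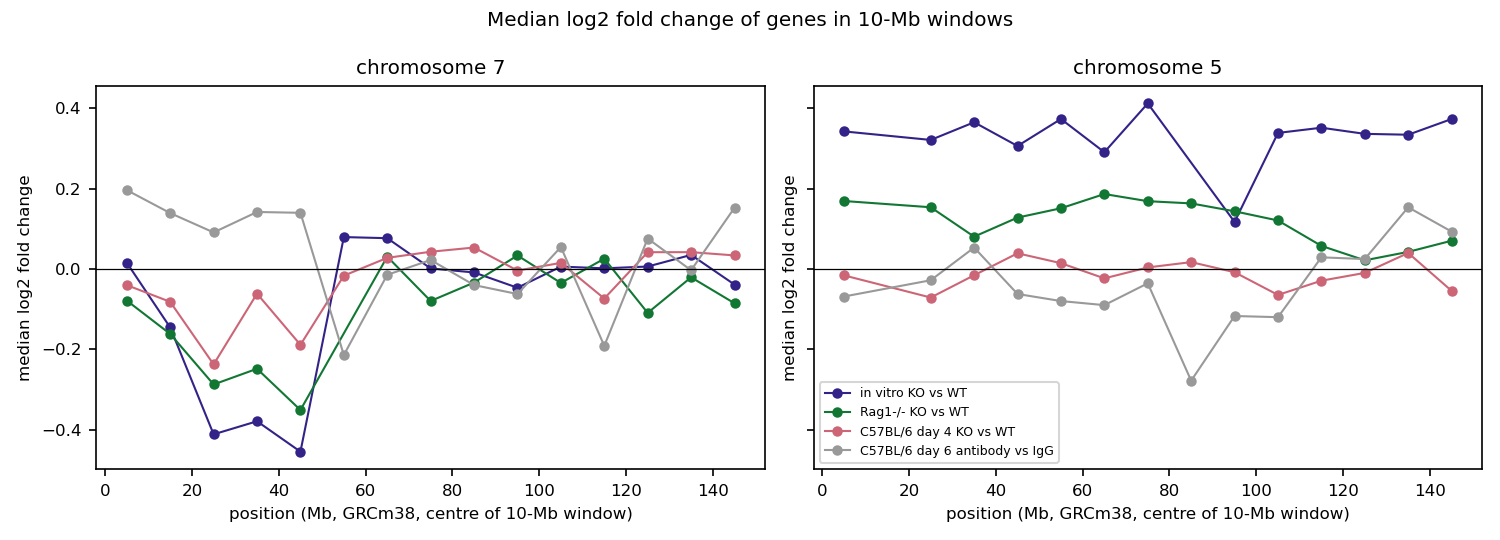
Median log2 fold change of genes in 10-Mb windows along chromosomes 7 and 5 (GRCm38) in the 4 comparisons. The segment of chromosome 7 between 20 and 50 Mb had medians of −0.41 in culture and −0.29 in Rag1-/- hosts.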

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

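Of the tests in this part, those of copy number, of luminal differentiation, of a smaller tumour share, of separate normalization and of other splits at day 6 were chosen only after the result was seen.

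In 10 groups 1 library lay far from the others, by a gap that took most of the group's range. Of 178 groups checked, chance gives about 1 in 20, or 8.9. Among knockout tumours in Rag1-/- hosts, library 3 was lowest in Map2k6 (gap 0.734 of the range) and in Prr19 (0.757). Among day 4 knockout tumours, library 5 was highest in Ddr1 (0.740) and lowest in Cldn4 (0.819), library 3 was highest in Krt14 (0.890) and library 2 lowest in Fosb (0.742). Among day 6 antibody tumours, library 1 was lowest in Clca3a2 (0.867), library 2 lowest in Stat2 (0.877) and library 4 lowest in Adm (0.8296). Among IgG tumours, library 1 was highest in Krt17 (0.959).

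The knockout effect differed between hosts, by a test of the difference, for 336 genes. The effect in C57BL/6 hosts was above that in Rag1-/- hosts by 1.499 for Jup, 1.32 for Acta2, 0.95 for Ptk7, 0.65 for Fads1 and 2.14 for Cacna1a. The same difference was −3.07 for Slc9a2, −2.36 for Chn1, −3.55 for Map2k6, −2.61 for Rnf165 and −3.13 for Tex19.2. Host, transplant history and table differed together here, and the higher luminal, keratinocyte and adipocyte markers of day 4 knockout tumours enter these differences too.

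Mouse Ddr1 was low in all 8 day 6 libraries, those given IgG included. Whether human DDR1 was expressed cannot be read from these counts of mouse genes. Separate normalization of the tables is argued against, since the log2 ratio of Ddr1 in RPM was −3.01 between day 6 IgG and day 4 wild-type tumours. Dilution of tumour cells by host cells is argued against too, since Syt16 lay above the highest day 4 wild-type library in 8 of 8 day 6 libraries. A candidate explanation, left a hypothesis as the labels give no genotype here, is that day 6 tumours grew from a knockout derivative, since Prr19, Espn and Syt16 lay on the knockout side of the day 4 midpoint in 24 of 24 values. The 8 Espn values carry no weight, since 8 of 8 wild-type libraries in culture and Rag1-/- hosts also lay on that side, and Prr19, at 0.318 RPM or less at day 6, was below every knockout library (0.992 or more), so the day 6 level did not match these derivatives.

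Luminal epithelial, keratinocyte and adipocyte genes were higher together in day 4 knockout and day 6 antibody tumours. For day 6, a smaller share of tumour cells that raised all host markers alike is argued against. The muscle median stayed at −3.66 or below with any 1 library left out, and luminal minus endothelial levels differed by 3.30 without overlap. By that difference a like rise was left open at day 4, where it was 1.73 with groups that overlapped (exact p = 0.0317 over splits). List medians with any 1 library left out argue against a like rise at day 4, for the lists they cover. They stayed at 3.01 or above for luminal and 2.67 or above for adipocyte markers, and ran from 1.31 to 2.69 for keratinocyte markers. For endothelial, fibroblast and T cell markers they were at most 1.51, 1.12 and 0.63. At neither day do these values test a smaller share with an uneven mix of host tissues. Cells of neighbouring gland, fat and skin may account for the pattern. Of 490 genes at least 2-fold higher at an unadjusted p under 0.05 at day 4, 75.1% had a mean under 10 in culture. Among all genes tested the share was 17.0%. That share does not separate neighbouring tissue from other host cells or from the tumour cells themselves. Krt18, Krt14 and Fabp4 averaged 520.1 ± 401, 1731 ± 3245 and 18809 ± 19829 in knockout tumours, with Krt14 far higher in knockout library 3. Luminal differentiation of the tumour cells cannot be told apart either. Adipocyte levels of the groups overlapped at both days, although the adipocyte median stayed at 2.63 or above with any 1 library left out. As markers of another cell type, adipocyte genes could not by themselves exclude differentiation of the tumour cells.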

How the results depend on the processing

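Array weights and the marker-based exclusions were tests chosen only after the data were seen. In culture the count of 39 changed genes became 12 without the trend, 1042 with DESeq2 and 1454 with array weights, and ranged from 2 (without wild-type library 2) to 1655 (without wild-type library 1), with 7 without wild-type library 3, 8 without knockout library 1 and 4 without knockout library 2. At day 4 the count of 5 became 9 with no filter on low values, 724 with DESeq2, 88 with array weights and 15 without the 2 libraries highest in muscle markers, and ranged from 3 (without wild-type library 2, 3 or 4) to 50 (without knockout library 5), with 13 without wild-type library 1 and 11 without knockout library 3. At day 6 the count of 0 became 155 with DESeq2 and ranged from 0 to 5 (without antibody library 1). In Rag1-/- hosts it ranged from 1984 to 3093 around 2904. With the replicate block the counts were 1 at day 4, 2411 in Rag1-/- hosts and 0 at day 6. Same-numbered libraries correlated at −0.204 to 0.446 and best with their own number in 0 of 4, 1 of 5 and 2 of 4 pairs. The numbers thus showed no clear pairing at day 4 or in Rag1-/- hosts. At day 6, pairs 1 and 4 correlated at 0.446 and 0.346, and 4 pairs cannot decide whether the numbers pair libraries. Among genes changed in at least 1 of 2 comparisons, r became 0.623 for culture and Rag1-/- hosts (2849 genes) and 0.153 for Rag1-/- hosts and day 4 (2863). It was 0.437 for culture and day 4 over 38 genes, with a Spearman of −0.0255, and −0.344 for culture and day 6 over 35. For day 4 and day 6 only 4 genes were left, with −0.168, or 0.296 without Ddr1, which decides nothing. Without the 2 libraries highest in luminal genes, the day 6 collagen list turned from lower to higher (camera adjusted p = 0.726). The cause was not tested. Of 2132 values of named genes under an alternative, 1993 kept their side of the threshold, as did 1100 of 1223 list values. Direction was compared only where the main or the alternative value passed the threshold, or for lists also the main one. Among such values 0 genes and 1 list reversed. Values past it in neither fit could change sign unseen. At the depth and spread of day 6, limma recovered 26% of simulated 2-fold changes, so changes of that size were mostly not detectable.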

Other observations

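In this part the test of copy number and that of other splits at day 6 were chosen only after the result was seen.

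Genes of chromosome 7 between 20 and 50 Mb were lower in the knockout, and the 3 lowest of 202 windows in culture and of 212 in Rag1-/- hosts were the 3 windows of this segment. By library in culture, the segment's median was −0.39 and −0.44 in the knockout derivatives and −0.03, −0.04 and 0.06 in the wild-type cells, while chromosome 5 was at 0.33 in each derivative. GC content and transcript length as the whole cause are argued against, since the median in Rag1-/- hosts went only from −0.29 to −0.24 after both were fitted. A copy number difference of the segment may account for it, since medians were −0.27 or lower in weakly and strongly expressed genes in culture and Rag1-/- hosts (lowest −0.57), although at day 4 they were −0.06 and −0.25. Whether loss of DDR1 itself lowers the segment cannot be told apart from a difference between derivatives, because the labels do not say how the empty vector and control cells were derived, and the day 6 median of 0.12 says little where both groups had low Ddr1.

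Other splits of the libraries were counted for each comparison with at least 3 per group. In Rag1-/- hosts 1 of 100 splits drawn, the real one, called as many genes (2904, highest other 422), which argues against a chance division of these tumours. It does not separate loss of Ddr1 from other differences between the knockout and wild-type cells. At day 4, 6 of 100 splits called 5 or more genes, so these splits do not exclude chance for the real count of 5. Of the 5 genes, 3 falls and 1 rise were shared with culture, against 0.0123 and 0.000176 for independent lists, which argues against chance for Ddr1, Espn, Prr19 and Syt16. The highest other called 1001, with wild-type library 1 and knockout libraries 1, 2 and 4 against the rest, and these 4 libraries had the highest adipocyte levels (9.54, 9.02, 12.68 and 12.27, against 8.58 or less). At day 6, 35 of 35 splits called as many as the real 0, and the highest other also called 0 by limma, where 1218 genes had an unadjusted p under 0.05 and edgeR called 0 and DESeq2 155. That outcome is fixed by the count of 0 and says nothing more.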
